A study of Mus musculus with 20 samples.

How the data were processed

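RNA of whole testes from 8-week-old mice of the inbred strains C57BL/6 and AKR/N was measured on the Affymetrix Mouse Genome 430 2.0 chip, an oligonucleotide array on which each transcript is read by a set of short probes. Each strain gave unheated controls and testes taken 8, 10, 12 and 24 h after heat shock at 43 °C for 15 min. The controls have no time of their own, so heat cannot be told apart from the time of sampling in comparisons with them. There were 10 groups of strain and time with 2 arrays each, 20 arrays in all, and all of them were used. Nothing in the labels says whether the 2 arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

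The deposited values are probe-set signals, in the unit intensity. Every array has the same trimmed mean, as a scaling of the arrays would give. The unit was read from the values, which are never negative and have a long tail of high values, as a linear scale gives. The mean without the top and bottom 2% of probe sets was 125.001 on every array. The software, the summary method and the scaling target are not given in the sources used here. The raw probe images were not used here. The replicate numbers in the labels did not pair samples across groups. The deviations of replicates from their group means correlated across genes with r from −0.28 to 0.30 in 45 pairs of groups, with a median of −0.01, and 4 of these exceeded 0.1.

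The table held 45101 probe sets, of which 64 control probe sets were left out of the tests. Of the other 45037, the chip annotation gave 1 gene for 34945, several genes for 932 and no gene for 9160, and only the first kind was used. Gene symbols are those of that annotation, and 34741 probe sets were matched to a reference by Entrez ID, which changed 0 symbols. Signals were taken as log2 of signal plus a pseudocount of 16. For each gene the probe set with the highest mean was kept, which gave 18194 genes, and 8480 of the genes tested had more than 1 probe set. The probe sets of 1543 tested genes carry a suffix that marks probes shared between transcripts. Genes were tested when the highest of their 10 group means reached the 40th percentile of the mean log2 values of all probe sets other than controls, a log2 value of 5.07 or a signal of 17.5, and 15762 genes remained. No genome coordinates were used. After seeing the data, the changes of the other probe sets that passed the same filter were computed for the named genes that were called, and most of those that ran the other way or came to less than 0.5 of the change are given.

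Tests were made with limma 3.58.1 in R 4.3.3, with the package data.table (1.17.8) and with matplotlib 3.10.9 in Python 3.11.15 for plots. A linear model with 1 mean per group was fitted to all 20 arrays, followed by empirical Bayes moderation of the variances (prior degrees of freedom 3.54, residual degrees of freedom 10). P-values were adjusted by the Benjamini-Hochberg method over the 15762 genes, and a gene was called at an adjusted p under 0.05. Every p given without another name is such a limma value, and the error given with a log2 change is its standard error (SE). The comparisons were AKR/N against C57BL/6 in controls and over the mean of all 5 conditions, heated against control within each strain (the mean of 4 times, and each time), the mean heat effect of both strains, 24 h against the mean of the earlier times, and the difference of the heat effect between strains (averaged over times, and at any time by limma's moderated F).

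Gene lists were tested with camera of limma at its preset correlation between genes of 0.01, and again with the correlation estimated from the data, each adjusted over 30 lists. The lists were heat shock chaperones, testis-specific chaperones, unfolded protein response, antioxidant defence, p53 targets, apoptosis machinery, immediate early and inflammatory genes, interferon-stimulated genes, hypoxia response, DNA repair, mitotic and meiotic division, cholesterol synthesis, blood-testis barrier junctions, MHC and antigen presentation, glutathione transferases and detoxification, and cold-inducible RNA-binding proteins. Lists of markers covered spermatogonia, early meiotic spermatocytes, pachytene spermatocytes, round spermatids, elongating spermatids, Sertoli cells, Leydig cells, peritubular myoid cells, macrophages and leukocytes, neutrophils, endothelial cells, red blood cells, epididymis and adipose tissue. For each list the count of called members is given over all genes tested and also adjusted over the list alone.

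The groups, the comparisons, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names, for each main comparison, up to 8 called genes per direction with the largest change among those whose arrays do not overlap between the groups. It also names up to 4 members per list with the smallest adjusted p, the 3 largest called rises and falls at each time, and a fixed set of genes of the heat response: Hspa1a, Hspa1b, Hsph1, Hspa8, Dnajb1, Hspb1, Hmox1, Cirbp, Rbm3, Hspa2, Cdkn1a and Bax. Of that set, 2 genes are not analysed here: Rbm3 is read only by probe sets shared with other genes, and Bax is not in the annotation. Trp53 is likewise absent from the annotation and Insl3 is read only by shared probe sets, so neither is analysed here. Genes outside the rule are said to have been chosen after their values were seen.

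The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter on dim genes or a filter at the 60th percentile, all probe sets in place of 1 per gene, a variance trend with robust moderation, a fit to only the groups compared, a replicate block, and leaving out each array in turn. Chosen after seeing the data were the difference of the heat effect between strains at each single time, the 24 h difference with the 8 h arrays as baseline, the mean 24 h effect of both strains, a covariate for the 3'/5' ratio of the beta-actin control probe sets, and a fit without 2 arrays that stood out. Random splits of the arrays (100 for each comparison) and intervals from 2000 bootstrap resamples of genes (95%) were drawn with fixed seeds. Splits that keep the 2 arrays of a group together (16 for strain and 25 for heat) were added after seeing the data. The fit was tested on simulated data with genes shifted by known amounts. Of genes shifted by 1 and by 0.5 log2 units it found 68% and 4% in C57BL/6 at 24 h, 60% and 16% at 8 h, and 62% and 16% between controls, all with 2 arrays against 2. It found 78% and 30% for the mean of 4 times in C57BL/6, and 34% and 2% for a difference of differences at 24 h. The runs of 2 arrays against 2 have the same simulated design, so their percentages differ only by the random draw. Each run shifted only 200 of the 15762 genes, far fewer than were called at 24 h, so the shares found in the data may differ. For arrays, their number limits the precision.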

Results

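Expression in whole testes was compared between C57BL/6 and AKR/N mice, unheated and 8, 10, 12 and 24 h after heat shock at 43 °C for 15 min. Each of the 10 groups of strain and time had 2 arrays. The median signal of an array lay between 24.9 and 34.9, the highest signal between 10460 and 13125, and 47.6 to 55.5% of probe sets lay under a signal of 32. Replicate arrays correlated across genes with r from 0.970 in C57BL/6 at 12 h to 0.988 in AKR/N at 8 h, where genes are not independent replicates. The 3'/5' signal ratio of beta-actin, a sign of RNA quality, ran from 1.87 to 3.57 and was highest in C57BL/6 12 h replicate 2. The first 3 principal components held 29.0, 20.03 and 11.8% of the variance. Changes are given as log2 differences of group means, each from 2 arrays per group unless said otherwise, with the SE of the limma fit. Because whole testes were measured, a change within cells cannot be told apart from a change in the mix of cells.

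The first comparison asked how unheated testes differ between the strains. Apoc2, which encodes an apolipoprotein, was higher in AKR/N by 4.22 (SE 0.43, adjusted p = 3.18e-05). Cd3d, a part of the T cell receptor complex, was higher by 3.85 (SE 0.28) and Vnn1, a pantetheinase, by 3.46 (SE 0.15). Lpo, 9430014N10Rik, Cyp2c55, Klb and Nmnat3 were higher by 3.27, 3.26, 3.18, 2.78 and 2.68. The transcript 1700104B16Rik was lower in AKR/N, with a difference of −5.03 (SE 0.13, adjusted p = 2.99e-11). Its signal was 987 in C57BL/6 and 14.6 in AKR/N, the latter under the 17.5 that defined a dim gene. Galntl6, 1700063D05Rik, 2010109A12Rik, Hoxb5os and 1700084F23Rik differed by −4.85, −4.58, −4.55, −4.22 and −3.69. Dapp1 differed by −3.89 but its other probe set by −0.84, and Stk36 by −3.58 but its other probe set by 0.12. Of 15762 genes, limma called 991, of which 488 were higher in AKR/N and 503 lower, and 341 differed at least 2-fold. With median centring 360 were higher and 555 lower, and with quantile normalization 444 and 530. In 57 of the genes that were lower and 90 of those that were higher, the strain with less signal lay under the threshold for dim genes. The count was 437 without AKR/N control replicate 1, 467 without C57BL/6 control replicate 1 and 442 without C57BL/6 control replicate 2.

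Class I and class II genes of the major histocompatibility complex gave lower signals in AKR/N controls. Whether their probes match the AKR/N sequence less well was not examined. H2-K1 differed by −2.56 (SE 0.19, adjusted p = 1.81e-06), H2-D1 by −2.49 (SE 0.28, adjusted p = 9.06e-05) and H2-Aa by −1.55 (SE 0.25, adjusted p = 0.00154). Other probe sets ran from −2.41 to −0.10 for H2-K1, from −2.55 to 2.07 for H2-D1 and from −1.04 to −0.37 for H2-Aa. H2-Ab1 differed by −1.82 (adjusted p = 0.00585), and its call ended without C57BL/6 control replicate 2 (−1.62, adjusted p = 0.07). In this list 0 genes were higher, 5 lower and 11 not passing, with 5 lower adjusted over the list alone, and camera gave adjusted p = 0.00575 (adjusted p = 0.44 with an estimated correlation). Leydig cell markers were higher in AKR/N, among them Star, which moves cholesterol into mitochondria for steroid synthesis, by 1.71 (SE 0.22, adjusted p = 2.45e-04, with 0.74 and 1.06 on other probe sets), and Hsd17b3, which makes testosterone, by 1.25 (SE 0.14, adjusted p = 7.57e-05). The list had 5 higher, 0 lower and 10 not passing, 8 higher adjusted over the list alone, and adjusted p = 2.11e-05 (adjusted p = 0.147 with an estimated correlation). Lin28a, a marker of undifferentiated spermatogonia, was higher by 1.91 (SE 0.22, adjusted p = 1.04e-04), but its other probe set was at −0.54. The spermatogonial list had 3 higher, 0 lower and 18 not passing, 5 higher adjusted over the list alone, and adjusted p = 0.0222 (adjusted p = 0.147 with an estimated correlation).

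Markers of macrophages and leukocytes were also higher in AKR/N controls. In that list 4 genes were higher, 0 lower and 17 not passing, 7 higher and 1 lower adjusted over the list alone, and adjusted p was 0.00114 (adjusted p = 0.277 with an estimated correlation). Csf1r, the receptor of a macrophage growth factor, differed by 0.75 (adjusted p = 0.00682, with 0.29 and 0.57 on other probe sets), a call that ended without AKR/N control replicate 1 (0.57, adjusted p = 0.0978) and without C57BL/6 control replicate 2 (0.68, adjusted p = 0.0775). Round spermatid markers were lower, with 0 higher, 4 lower and 23 not passing, 8 lower adjusted over the list alone, and adjusted p = 2.11e-05 (adjusted p = 0.44 with an estimated correlation). Actl7b, an actin-related protein of spermatids, differed by −0.74 (adjusted p = 0.0122). Its call ended without AKR/N control replicate 1 (−0.50, adjusted p = 0.155), C57BL/6 control replicate 1 (adjusted p = 0.0756) or C57BL/6 control replicate 2 (adjusted p = 0.0801). These 5 of 30 lists were called with the preset correlation, and 0 with the estimated one. None of the genes of the heat response named beforehand was called between the controls. Hspa1b differed by 1.67 (adjusted p = 0.167), but with AKR/N control replicate 1 left out it was called at 2.99 (adjusted p = 0.00731).

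Averaged over the 5 conditions, with 10 arrays per strain, 4379 genes differed between the strains, 2342 higher in AKR/N and 2037 lower, and 258 at least 2-fold. Median centring turned the balance to 1907 higher and 2233 lower. The transcript 1700104B16Rik differed by −4.25 (adjusted p = 5.65e-15) and Hsd17b3 by 1.04 (adjusted p = 2.32e-08), while Star differed by 0.06 (adjusted p = 0.702). Round spermatid markers were lower in AKR/N, with 1 higher, 16 lower and 10 not passing, 1 higher and 19 lower adjusted over the list alone, and adjusted p = 7.76e-07 (adjusted p = 0.446 with an estimated correlation). Elongating spermatid markers had 1 higher, 12 lower and 13 not passing, the same counts adjusted over the list alone, and adjusted p = 3.86e-04 (adjusted p = 0.573 with an estimated correlation). Macrophage and leukocyte markers had 11 higher, 0 lower and 10 not passing, 12 higher adjusted over the list alone, and adjusted p = 3.86e-04 (adjusted p = 0.446 with an estimated correlation). Of the 7 lists called, 0 held with an estimated correlation.

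The next comparison asked what heat shock changed in C57BL/6 testes, taking the mean of the 4 times (8 heated arrays against 2 controls). Hspa1b and Hspa1a, near-identical genes of the inducible chaperone HSP70, rose by 5.26 (SE 0.52, adjusted p = 8.29e-05) and 4.01 (SE 0.53, adjusted p = 4.04e-04). The small heat shock proteins Cryab and Hspb1 rose by 2.63 (SE 0.18) and 2.09 (SE 0.12), where 1 of the 2 other probe sets of Cryab rose by only 0.36. The mitochondrial chaperones Hspd1 and Hspe1 rose by 2.35 (SE 0.13) and 2.28 (SE 0.15), and the cytosolic chaperones Hspa8 and Hsph1 by 1.40 and 1.08. Hmox1, a heme oxygenase induced by oxidative stress, rose by 2.51 (SE 0.32, adjusted p = 3.19e-04), and Cdkn1a, an inhibitor of the cell cycle, by 2.03 (SE 0.20, adjusted p = 9.44e-05), or by 1.02 on its other probe set. Star rose by 2.40 (SE 0.17, adjusted p = 4.87e-06), and the stress-response genes Egr1, Tnfrsf12a and Atf3 by 3.44, 2.78 and 2.64. Dnajb1, a partner of HSP70, changed by −0.04 and was not called (adjusted p = 0.824).

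Among the falls in heated C57BL/6 testes, Aym1 fell by 1.62 (SE 0.19, adjusted p = 2.26e-04), and changes were −1.55 for Zfp389 and Elfn2, −1.54 for Lef1, −1.46 for 4931408D14Rik and −1.39 for Rnf112. Msi2 and Vapb fell by 1.46, but the other probe sets of Msi2 moved by −0.31 to 0.40 and those of Vapb by 0.15 to 0.23. Other probe sets moved by −0.59 for Lef1 and by −0.59 and −0.55 for Rnf112. Hspa2, the HSP70 of spermatocytes, fell by 0.67 (SE 0.14, adjusted p = 0.00437), a call that ended without C57BL/6 control replicate 2 (−0.63, adjusted p = 0.0732). Cirbp, a cold-inducible RNA-binding protein, fell by 0.48 (SE 0.12, adjusted p = 0.00989), which ended without C57BL/6 control replicate 1 (−0.41, adjusted p = 0.129) or replicate 2 (−0.55, adjusted p = 0.0571). The test called 3378 genes, of which 1754 rose, 1624 fell and 198 changed at least 2-fold. The balance turned to 1400 up and 1729 down with median centring and to 1681 and 1706 with quantile normalization. Without C57BL/6 control replicate 1 there were 1326 and without replicate 2 there were 1021.

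Heat shock chaperones rose as a list in C57BL/6, with 14 up, 0 down and 11 not passing, 15 up adjusted over the list alone, and adjusted p = 1.94e-09 (0.0176 with an estimated correlation). Targets of p53 had 11 up, 1 down and 9 not passing, 16 up and 1 down adjusted over the list alone, and adjusted p = 4.2e-06 (0.0216 with an estimated correlation). In this list Ccng1 and Gadd45a rose by 1.84 (0.70 and 1.02 on other probe sets of Ccng1) and 1.28 while Zmat3 fell by 0.55. The hypoxia response list, with Pgk1 and Slc2a1 up by 0.79 and 0.78, had 9 up, 0 down and 8 not passing, 10 up adjusted over the list alone, and adjusted p = 2.85e-04 (0.0216 with an estimated correlation). The mitotic and meiotic division list fell, with changes of −0.94 for Nek2, a kinase of the centrosome (−0.83 to 0.11 on its other probe sets), and −0.73 for Aurkc, a meiotic kinase. It had 0 up, 14 down and 9 not passing, 14 down adjusted over the list alone, and adjusted p = 1.8e-07 (adjusted p = 0.192 with an estimated correlation). Pachytene spermatocyte markers fell too, among them Piwil1, which binds piRNAs, with −1.14 (SE 0.13). That list had 2 up, 11 down and 14 not passing, 3 up and 13 down adjusted over the list alone, and adjusted p = 4.42e-04 (adjusted p = 0.192 with an estimated correlation), and the members that rose were Pgk2 (0.33) and Taf7l (0.40). The calls of Zmat3, Pgk2 and Taf7l ended without C57BL/6 control replicate 1 (adjusted p = 0.166, 0.121 and 0.0622) and without replicate 2 (0.0928, 0.111 and 0.0899).

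Immediate early and inflammatory genes, with Ier3 up by 2.06 and Klf6 by 1.39, had 14 up, 0 down and 12 not passing in C57BL/6, 15 up adjusted over the list alone, and adjusted p = 3.39e-07 (adjusted p = 0.108 with an estimated correlation). Interferon-stimulated genes, with Oasl2 up by 1.14, had 8 up, 0 down and 9 not passing, 10 up adjusted over the list alone, and adjusted p = 3.56e-05 (adjusted p = 0.0973 with an estimated correlation). Antioxidant defence had 9 up, 1 down and 13 not passing, 10 up and 1 down adjusted over the list alone, and adjusted p = 0.00165 (adjusted p = 0.0873 with an estimated correlation), and its member that fell was Sod2 (−0.42), which lost its call without C57BL/6 control replicate 1 (adjusted p = 0.159) or replicate 2 (adjusted p = 0.142). Glutathione transferases and detoxification had 11 up, 2 down and 13 not passing, 11 up and 3 down adjusted over the list alone, and adjusted p = 0.0103 (adjusted p = 0.311 with an estimated correlation). Cholesterol synthesis had 4 up, 1 down and 12 not passing, 6 up and 1 down adjusted over the list alone, and adjusted p = 0.0177 (adjusted p = 0.0973 with an estimated correlation).

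Among cell-type markers in heated C57BL/6 testes, elongating spermatid genes had 7 up, 0 down and 19 not passing, 9 up adjusted over the list alone, and adjusted p = 3.63e-04 (adjusted p = 0.341 with an estimated correlation). Leydig cell genes had 4 up, 0 down and 11 not passing, 4 up adjusted over the list alone, and adjusted p = 0.00663 (adjusted p = 0.192 with an estimated correlation). Sertoli cell genes, with Clu up by 0.59 and Sox8 changed by −0.52, had 8 up, 1 down and 15 not passing, the same counts adjusted over the list alone, and adjusted p = 0.00847 (adjusted p = 0.192 with an estimated correlation). The call of Sox8 ended without either C57BL/6 control (adjusted p = 0.205 and 0.167 without replicates 1 and 2) and without each of 4 heated arrays in turn. Peritubular myoid cell genes had 5 up, 0 down and 9 not passing, 7 up adjusted over the list alone, and adjusted p = 0.0223 (adjusted p = 0.192 with an estimated correlation).

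The other 16 lists were not called in C57BL/6. The counts up, down and not passing were 3, 2 and 6 for testis-specific chaperones (3 up and 3 down adjusted over the list alone, adjusted p = 0.506), 4, 3 and 19 for the unfolded protein response (4 up and 3 down, adjusted p = 0.663) and 5, 4 and 20 for the apoptosis machinery (7 up and 4 down, adjusted p = 0.506). For DNA repair they were 0, 1 and 20 (0 adjusted over the list alone, adjusted p = 0.876), for blood-testis barrier junctions 3, 0 and 15 (3 up, adjusted p = 0.0805) and for MHC and antigen presentation 1, 1 and 14 (1 up and 1 down, adjusted p = 0.876). The last of these had a median of −0.06, a mean of 0.05 and a test direction of up. Spermatogonia had 4, 1 and 16 (4 up and 1 down adjusted over the list alone, adjusted p = 0.506), early meiotic spermatocytes 3, 2 and 19 (3 up and 3 down, adjusted p = 0.876) and round spermatids 7, 2 and 18 (9 up and 3 down, adjusted p = 0.355). Macrophages and leukocytes had 2, 0 and 19 (0 adjusted over the list alone, adjusted p = 0.128) and endothelial cells 1, 0 and 14 (0, adjusted p = 0.113). Neutrophils had 0, 0 and 8 (adjusted p = 0.876) and red blood cells 0, 0 and 4 (adjusted p = 0.741), each with 0 adjusted over the list alone. Adjusted over the list alone, epididymis (0, 1 and 6) kept 1 down (adjusted p = 0.919), adipose tissue (1, 0 and 7) 1 up (adjusted p = 0.716) and cold-inducible RNA-binding proteins (0, 1 and 2) 1 down (adjusted p = 0.506).

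Time by time in C57BL/6, 2 arrays against 2, 14 genes rose at 8 h and 0 fell in limma, where 1209 genes had an unadjusted p under 0.05. Hspa1b rose by 6.40, 6.03, 5.86 and 2.74 at 8, 10, 12 and 24 h. Its 24 h call ended without C57BL/6 24 h replicate 1 (2.24, adjusted p = 0.0567). Cryab, Hspb1, Hspd1, Hspe1, Star and Cyp11a1 were among the 14 at 8 h, chosen for mention after their values were seen. Cdkn1a changed by 0.35 at 8 h, where it was not called, and rose by 2.36, 2.89 and 2.52 at 10, 12 and 24 h, against 1.17, 1.25 and 0.97 on its other probe set. At 10 h 946 genes rose and 818 fell, and Kctd14 and Vapb fell by 1.92, with other probe sets of Vapb at −0.02 and 0.33. At 12 h 1531 rose and 1479 fell (1147 and 1577 with median centring, 1415 and 1565 with quantile normalization), while Tnfrsf12a rose by 3.46 and Zfp688 fell by 2.45. At 24 h 3366 rose and 2623 fell, 1775 of them at least 2-fold, with Tnfrsf12a up by 4.21 (SE 0.36), Ccng1 by 3.14 (SE 0.22) and Adh1 by 3.04 (SE 0.22), while Pabpc6 changed by −2.72 (SE 0.18), Lef1 by −2.66 (SE 0.33) and Cabcoco1 by −2.49 (SE 0.20). Median centring moved the median change of all genes at 24 h by −0.14, from 0.08 to −0.06, and the share of called genes that rose from 56.2 to 42.7%. On other probe sets the 24 h change was 1.27 and 1.68 for Ccng1 and −1.13 for Lef1. At 8 h Leydig cell genes had adjusted p = 3.83e-11 (0.00996 with an estimated correlation), with 2 up, 0 down and 13 not passing and 6 up adjusted over the list alone.

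Single arrays moved the C57BL/6 counts at single times. At 8 h there were 4 genes without 8 h replicate 1 or control replicate 2, and 3 without 8 h replicate 2 or control replicate 1, and Hspa1b, Cryab and Hspb1 were called each time. At 10 h there were 675 without 10 h replicate 1, 534 without 10 h replicate 2, 362 without control replicate 1 and 502 without control replicate 2, against 1764. At 12 h there were 1716 without 12 h replicate 2, 1422 without control replicate 1 and 1194 without control replicate 2, against 3010. With the beta-actin ratio as a covariate, chosen after seeing the data, the 12 h count was 1091. All 3010 changes kept their sign, with a median ratio of 0.956 to their former size, while the median SE grew from 0.164 to 0.210. At 24 h the count of 5989 stayed between 4071 and 4555 with any 1 of its 4 arrays left out.

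**Figure D1:**
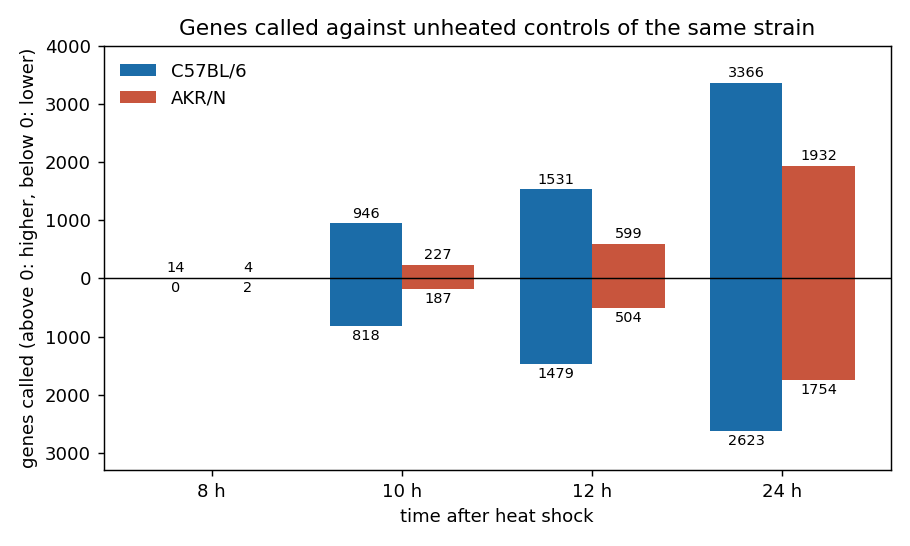
Bars give the number of genes called by limma against the unheated controls of the same strain at each time in hours, risen above 0 and fallen below it, with 2 arrays per group. At 24 h, 3366 genes rose and 2623 fell in C57BL/6, and 1932 rose and 1754 fell in AKR/N.

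The same question was put to AKR/N testes, again over the mean of the 4 times. Cryab rose by 2.89 (SE 0.18, adjusted p = 3.34e-06; 0.17 and 2.50 on other probe sets), Hspb1 by 1.93 (SE 0.12, adjusted p = 3.34e-06), Hspd1 by 1.67 (SE 0.13, adjusted p = 4.56e-05), Hspe1 by 1.62 (0.80 on its other probe set) and Hspa8 by 0.97. Hmox1 rose by 2.24 (SE 0.32, adjusted p = 0.00397), Maff by 1.67, Adamts1 by 1.48, Hsph1 by 0.96 and Cdkn1a by 1.36 (adjusted p = 0.00499). Hspa1b rose by 2.94 (SE 0.52, adjusted p = 0.00946) and Hspa1a by 2.47 (SE 0.53, adjusted p = 0.0244). Hspa2 changed by −0.52 (adjusted p = 0.0505), Cirbp by −0.16 (adjusted p = 0.462) and Dnajb1 by 0.19 (adjusted p = 0.316), and these were not called. Emx2 fell by 1.05 and Cnnm4 fell by 1.15, while the other probe sets of Cnnm4 moved by −0.20 and −0.14. Vapb fell by 1.63, where its other probe sets moved by 0.05 and 0.44. The test called 677 genes, 377 up and 300 down, 50 of them at least 2-fold.

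The AKR/N calls rested on the control arrays, and their number moved with a covariate for RNA quality. The 3'/5' beta-actin ratio was 2.92 and 2.39 in AKR/N controls, 1.91 and 1.93 at 8 h, and 1.87 and 1.99 at 10 h. At 12 h it was 2.74 and 2.62, and at 24 h 2.14 and 2.17. With that ratio as a covariate, chosen after seeing the data, the count of 677 became 42. Over the 677 genes, which all kept their sign, the median size of the change went from 0.58 to 0.52 and the median SE grew from 0.123 to 0.158, so that 37 of them were called. Without AKR/N control replicate 1 there were 20 genes, and adjusted p was 0.0579 for Hmox1, Maff, Adamts1, Hsph1, Vapb and Cnnm4, 0.0848 for Cdkn1a, 0.128 for Emx2, 0.169 for Hspa1b (1.61) and 0.314 for Hspa1a (1.48). Bhlhe40 (1.47), Slc45a2 (−1.27), Mysm1 (−1.26), Tasor (−1.18), Nkpd1 (−1.10) and Kbtbd11 (−1.06) were called with all arrays, but without that control their adjusted p lay between 0.187 and 0.381. The other probe sets of Mysm1 rose by 0.35 and 0.59, that of Slc45a2 was at 0.03 and that of Kbtbd11 at −0.54. Hspa1b and Hspa1a were raised in AKR/N control replicate 2. Their rise is therefore smaller without control replicate 1, and larger without control replicate 2. Without AKR/N control replicate 2 there were 208 genes, and the calls of Bhlhe40 (adjusted p = 0.215), Mysm1 (0.0825), Tasor (0.113), Nkpd1 (0.0596) and Kbtbd11 (0.141) ended. Calls of Bhlhe40, Slc45a2, Tasor or Kbtbd11 also ended when 1 of the 8 heated arrays was left out, with adjusted p up to 0.0719. The count was 421 without AKR/N 8 h replicate 1, 346 without 8 h replicate 2 and 333 without 24 h replicate 2.

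As lists, heat shock chaperones in AKR/N had 12 up, 0 down and 13 not passing, 14 up adjusted over the list alone, and adjusted p = 4.88e-16 (0.00221 with an estimated correlation). Targets of p53 had 3 up, 0 down and 18 not passing, 7 up and 1 down adjusted over the list alone, and adjusted p = 1.38e-05 (0.0409 with an estimated correlation). Immediate early and inflammatory genes had 7 up, 0 down and 19 not passing, 10 up adjusted over the list alone, and adjusted p = 1.5e-07 (adjusted p = 0.127 with an estimated correlation). Antioxidant defence had 4 up, 0 down and 19 not passing, 7 up adjusted over the list alone, and adjusted p = 9e-04 (adjusted p = 0.0507 with an estimated correlation). The hypoxia response had 4 up, 0 down and 13 not passing, 5 up adjusted over the list alone, and adjusted p = 0.00838 (adjusted p = 0.0507 with an estimated correlation). Glutathione transferases and detoxification had 1 up, 0 down and 25 not passing, 6 up and 2 down adjusted over the list alone, and adjusted p = 0.0159 (adjusted p = 0.438 with an estimated correlation). Round spermatid markers were called as rising at adjusted p = 0.0272 (adjusted p = 0.561 with an estimated correlation), though 0 members rose, 1 fell and 26 did not pass, with 4 up and 1 down adjusted over the list alone. The member that fell, Pou5f2 (−0.53), lost its call without AKR/N control replicate 1 (adjusted p = 0.225), control replicate 2 (0.101) or 8 h replicate 2 (0.0507).

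At 8 h in AKR/N, 4 genes rose and 2 fell, 1568 genes had an unadjusted p under 0.05, and median centring changed the share of called genes that rose from 66.7 to 85.7%. Hspa1b rose by 4.77, Cryab by 1.90, Hspb1 by 1.60 and Adamts1 by 1.52, and Zscan29 and Themis changed by −1.12 and −0.97, called as falls, Adamts1 being chosen after its value was seen. The other probe set of Themis was at 0.56, and those of Cryab at 0.04 and 1.69. Without 8 h replicate 1 or control replicate 1 only Hspb1 was called, and without 8 h replicate 2 only Hspb1 and Cryab. At 10 h 227 genes rose and 187 fell, with Hspa1b up by 4.45, Hspa1a by 4.11 and Atf3 by 3.29. At 12 h 599 rose and 504 fell, with Cryab up by 3.59 (−0.01 and 3.14 on other probe sets), Hmox1 by 3.55 and Hspa1b by 3.41, and Slco1a4 fell by 1.75. At 24 h 1932 rose and 1754 fell, 630 at least 2-fold, with Cryab up by 3.38 (SE 0.23), Tnfrsf12a by 2.39 (SE 0.36) and Sema5a by 2.35 (SE 0.25), while 4930478P22Rik changed by −2.49 (SE 0.41), Ube2s by −2.21 (SE 0.16) and Vapb by −2.14 (SE 0.26). On other probe sets the 24 h change was 0.32 and 2.65 for Cryab, 0.53 and 1.85 for Sema5a, 0.10 for Ube2s, and 0.31 and 0.47 for Vapb. Hspa1b stood at −0.86 at 24 h and was not called. Its control mean was raised by AKR/N control replicate 2, and the sign of this change rests on that array. Median centring changed the share of called genes that rose at 24 h from 52.4 to 41.5%, and quantile normalization to 48.3%.

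Single arrays moved the AKR/N counts at single times. With the beta-actin covariate the counts of 6, 414 and 3686 at 8, 10 and 24 h became 2, 15 and 1955. Over the genes called without it the changes kept their sign, with median ratios of 0.961, 0.985 and 0.939 to their former size, while the median SE grew from 0.201, 0.163 and 0.168 to 0.274, 0.228 and 0.195. At 10 h the count of 414 was 52 without 10 h replicate 1, 158 without 10 h replicate 2, 33 without control replicate 1 and 183 without control replicate 2. The 10 h call of Hspa1a ended without 10 h replicate 1 (adjusted p = 0.0647) or control replicate 1 (3.12, adjusted p = 0.109), and that of Atf3 ended without any 1 of its 4 arrays (adjusted p from 0.0549 to 0.133). At 12 h the count of 1103 was 171 without 12 h replicate 1, 359 without control replicate 1 and 471 without control replicate 2. The 12 h call of Hspa1b ended without 12 h replicate 1 (2.99, adjusted p = 0.0991) or control replicate 1 (2.08, adjusted p = 0.063). At 24 h the count of 3686 was 1073 without 24 h replicate 2, 2116 without control replicate 1 and 2281 without control replicate 2.

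**Figure D2:**
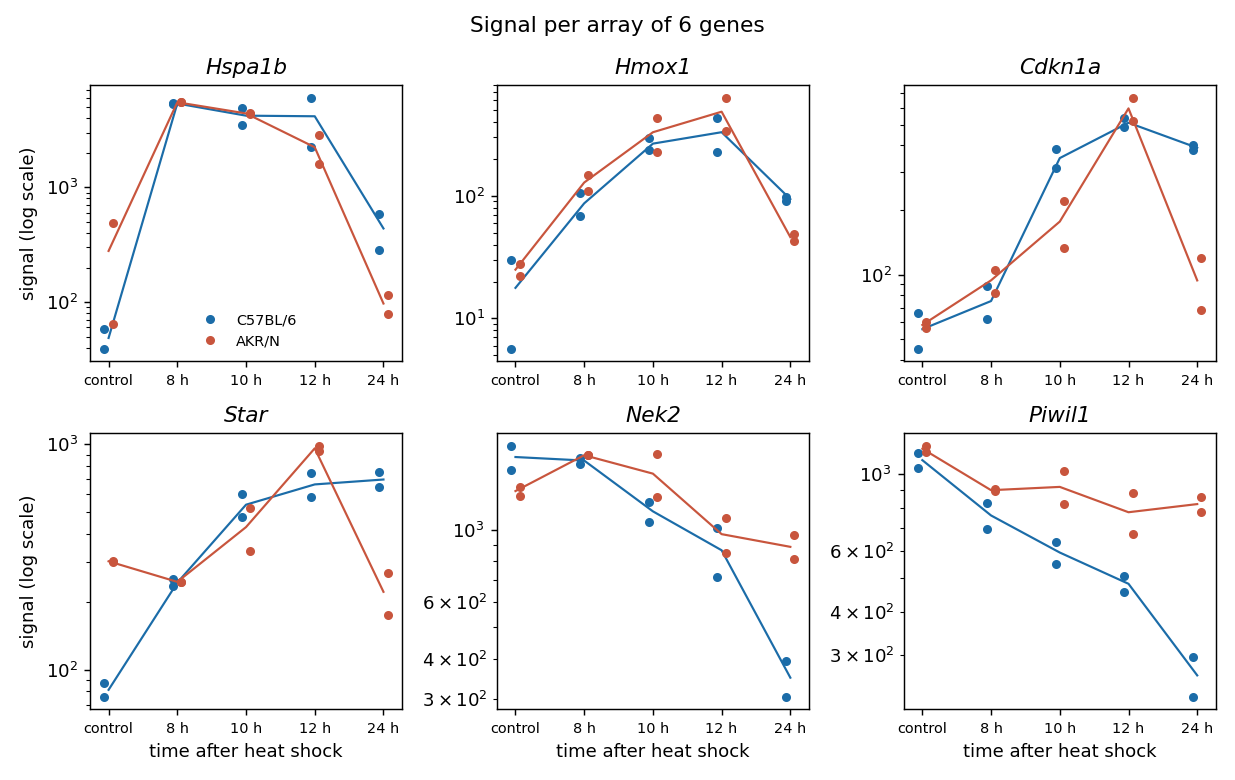
Points are the signal of Hspa1b, Hmox1, Cdkn1a, Star, Nek2 and Piwil1 on each array on a log scale, and lines join the means of 2 arrays over control and the 4 times in hours. Hspa1b lay at 64.7 and 493 on the 2 AKR/N control arrays.

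A comparison of both strains asked whether the heat effects run in parallel. Over the mean of both strains, Hspb1 rose by 2.01 (SE 0.08), Hspa8 by 1.18 (SE 0.06), Hmox1 by 2.38 (SE 0.22) and Cdkn1a by 1.70 (SE 0.14), and Hspa2 fell by 0.60 (SE 0.10, adjusted p = 7.97e-04). Cirbp fell by 0.32 (SE 0.08, adjusted p = 0.0111), which ended without AKR/N control replicate 1 (−0.24, adjusted p = 0.0847) or C57BL/6 control replicate 1 (−0.28, adjusted p = 0.067). With 16 heated and 4 control arrays, 4101 genes were called, 2059 up and 2042 down (1821 and 2096 with median centring, 2028 and 2172 with quantile normalization), and 2527 without C57BL/6 control replicate 2. Across genes, which are not independent replicates, the heat effects of the strains correlated with r = 0.25 at 8 h, 0.40 at 10 h, 0.58 at 12 h and 0.64 at 24 h. At 24 h 1475 genes rose in both strains where 412.6 would by chance, 1180 fell in both where 291.9 would, and 31 were called in opposite directions. In the mean of both strains 4 of 14 called lists held with an estimated correlation: heat shock chaperones (0.00664), p53 targets (0.0157), hypoxia response (0.0157) and antioxidant defence (0.0374).

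**Figure D3:**
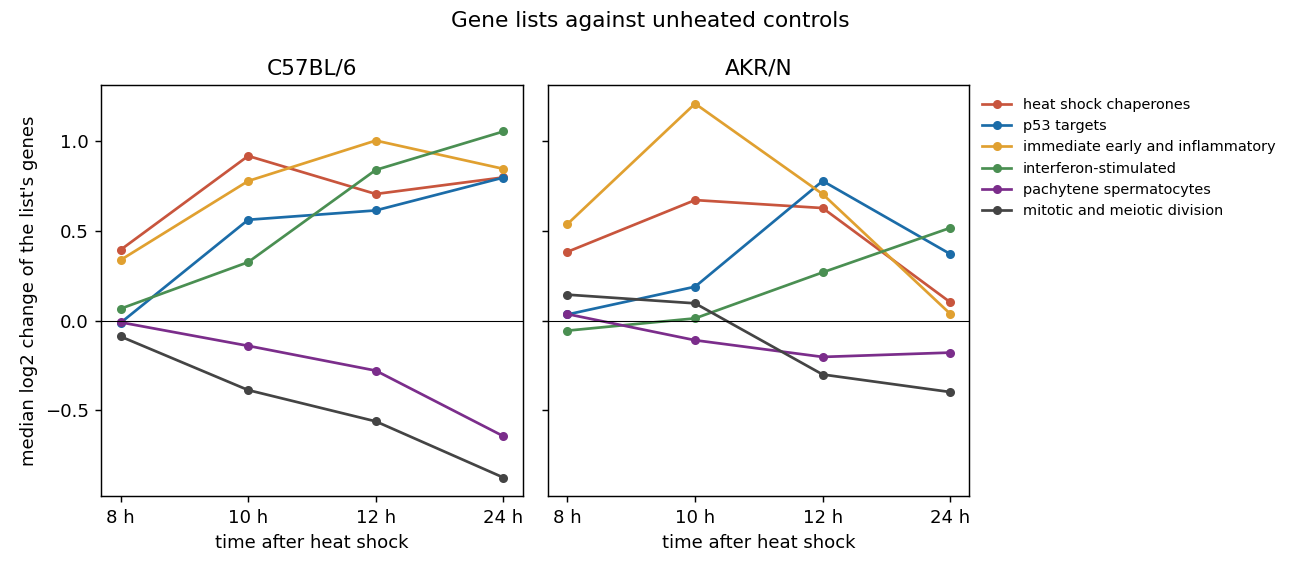
Lines give the median log2 change of the genes of 6 lists against the unheated controls of the same strain at 8, 10, 12 and 24 h. At 24 h the median of the mitotic and meiotic division list was −0.88 in C57BL/6 and −0.40 in AKR/N.

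The late change was asked for by comparing 24 h with the mean of 8, 10 and 12 h. Hspa1b fell by 3.35 (SE 0.54, adjusted p = 5.56e-04) in C57BL/6 and fell by 5.07 (SE 0.54, adjusted p = 1.14e-04) in AKR/N. Hspa8 changed by −0.53 (SE 0.09) and −1.06 (SE 0.09), a fall in both. Hmox1 fell by 2.19 (SE 0.33, adjusted p = 5.63e-04) in AKR/N. Blood-testis barrier junction genes rose late, with 10 up, 0 down and 8 not passing in C57BL/6, 10 up adjusted over the list alone, and adjusted p = 0.00257 (adjusted p = 0.263 with an estimated correlation). In AKR/N this list had 9 up, 0 down and 9 not passing, 9 up adjusted over the list alone, and adjusted p = 1.23e-04 (adjusted p = 0.106 with an estimated correlation). The mitotic and meiotic division list fell late in C57BL/6, with 1 up, 14 down and 8 not passing, 1 up and 17 down adjusted over the list alone, and adjusted p = 3.95e-08 (adjusted p = 0.285 with an estimated correlation). In AKR/N it had 1 up, 9 down and 13 not passing, 1 up and 10 down adjusted over the list alone, and adjusted p = 0.00169 (adjusted p = 0.455 with an estimated correlation). In C57BL/6 4521 genes changed late, 2612 up and 1909 down, and the count was 1872 without 24 h replicate 1 and 2728 without replicate 2. In AKR/N 3941 changed, 2208 up and 1733 down, and the count was 2553 without 24 h replicate 1 and 909 without replicate 2. Median centring moved the median of all genes by −0.13 in C57BL/6 and changed the share of called genes that rose from 57.8 to 37.6% there and from 56.0 to 38.0% in AKR/N.

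The last comparison asked whether the heat effect differed between the strains, as the interaction of strain and heat. Averaged over times, the rise of Star was smaller in AKR/N, with a difference of −2.07 on the log2 scale (adjusted p = 0.0125). Part of this difference lay in the controls, where Star was higher in AKR/N by 1.71. Over the mean of the 5 conditions Star differed by only 0.06. Cd24a, a surface glycoprotein, differed by −1.21 (adjusted p = 0.0412) and 1700104B16Rik by 0.98 (adjusted p = 0.0428), the latter with AKR/N signals of only 14.6 in controls and 13.4 at 24 h. These 3 genes, 1 with a positive and 2 with a negative difference (AKR/N minus C57BL/6), were the only ones called, and 2016 had an unadjusted p under 0.05. The share with a positive difference went from 33.3% to 0 with median centring and 50% with quantile normalization. Without AKR/N control replicate 1 or C57BL/6 control replicate 1 there were 0, and the adjusted p of Star was then 0.169 or 0.104. Without C57BL/6 control replicate 2 the call of Star ended too (adjusted p = 0.0964), and the 1 gene called was Map3k2 (−1.63), chosen for mention after its value was seen. With the beta-actin ratio as a covariate limma called 0 genes, 1278 had an unadjusted p under 0.05, and Star had a difference of −2.27 with an adjusted p of 0.125. Over the 3 genes, which kept their sign, the median size went from 1.21 to 1.08 and the median SE grew from 0.168 to 0.218. On other probe sets the averaged difference was −1.03 and −0.83 for Star and −0.48 and −0.06 for Cd24a. The count lay between 0 and 7 over all arrays left out in turn, and 16 of 20 arrays moved it by more than 1.5 times. A test at any time called 13 genes, with 3 to 27 when 1 array was left out, and 2422 had an unadjusted p under 0.05.

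At single times, tests that were chosen after seeing the data called 0 genes at 8 h and 0 at 12 h in limma, where 892 and 1477 had an unadjusted p under 0.05. With a variance trend and robust moderation there were 2 at 8 h, Star and Cyp11a1, and with a pseudocount of 64 or a filter at the 60th percentile 1 at 12 h, 1700104B16Rik. Without AKR/N 12 h replicate 2 a different gene was called at 12 h, Hebp1 (2.47, adjusted p = 0.036), chosen for mention after its value was seen. At 10 h 5 genes were called, Star (−2.05, SE 0.31), Smc4 (1.96, SE 0.26), Aldh18a1 (−1.55, SE 0.19), 1700104B16Rik (1.27, SE 0.18) and Morf4l2 (−1.42, SE 0.22), and 1941 had an unadjusted p under 0.05. On other probe sets the difference ran from −0.84 to −0.70 for Star, from 0.24 to 0.55 for Smc4 and from −0.58 to 0.05 for Aldh18a1. The AKR/N control signal of 1700104B16Rik, 14.6, lay under the threshold for dim genes. It could hardly fall there, while it changed by −0.97 in C57BL/6 at 10 h. The 10 h count was 0 without AKR/N 10 h replicate 2, AKR/N control replicate 1, C57BL/6 10 h replicate 1, C57BL/6 10 h replicate 2 or C57BL/6 control replicate 1, and 2 without C57BL/6 control replicate 2. The share with a positive difference went from 40% to 66.7% with quantile normalization.

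At 24 h 277 genes had a heat effect that differed between the strains, of which 240 changed less in AKR/N. Star rose by 2.87 in C57BL/6 and changed by −0.45 in AKR/N, a difference of −3.33 (SE 0.31, adjusted p = 3.5e-04). Gadd45a and Cdkn1a, which respond to p53, rose by 1.74 and 2.52 in C57BL/6 and changed by 0.09 and 0.53 in AKR/N. The differences were −1.65 (SE 0.24) and −1.99 (SE 0.36). At 10 and 12 h Cdkn1a had risen in AKR/N too, by 1.34 and 3.03, against 2.36 and 2.89 in C57BL/6. Its level at 24 h against the earlier times changed by −1.11 in AKR/N and 0.65 in C57BL/6. The other probe set of Cdkn1a gave −0.28 and −0.07 for this late change. Hspd1 rose by 2.71 in C57BL/6 and 1.30 in AKR/N, a difference of −1.41 (SE 0.24). Piwil1 and Nek2 fell in C57BL/6 (−2.01 and −2.22) and stood at −0.52 and −0.57 in AKR/N, with differences of 1.48 (SE 0.24) and 1.65 (SE 0.28). Boll, a germ cell gene, fell by 1.18 in C57BL/6 and changed by 0.37 in AKR/N (difference 1.55, SE 0.32). Other probe sets gave smaller or opposite differences: −1.88 and −1.42 for Star, −0.07 for Cdkn1a, −0.16 to 1.64 for Nek2 and −1.63 to 0.93 for Boll. For Hspa1b the difference was −3.60 and was not called (adjusted p = 0.0633). Its levels (AKR/N minus C57BL/6) differed by −1.94 at 24 h and by 1.67 in controls, where AKR/N control replicate 2 was raised. Of the 277, 171 were called in C57BL/6 alone, 22 in AKR/N alone, 56 in both with the same sign and 28 in both with opposite signs. In 10 of them both AKR/N means lay under the threshold for dim genes. Of 6904 genes called in the mean of both strains at 24 h, 70.9% changed more in C57BL/6, with a median size of 0.71 against 0.51.

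The 24 h difference rested on few arrays. The count was 2, Star and Cd24a, without AKR/N 24 h replicate 1, and 92 without AKR/N 24 h replicate 2. It was 11 without AKR/N control replicate 1, 122 without AKR/N control replicate 2, 15 without C57BL/6 24 h replicate 1, 62 without C57BL/6 24 h replicate 2, 19 without C57BL/6 control replicate 1 and 16 without C57BL/6 control replicate 2. Star kept its call with each of these left out. The calls of Hspd1, Cdkn1a, Gadd45a, Piwil1, Nek2 and Boll ended without AKR/N 24 h replicate 1, with adjusted p between 0.0702 and 0.106, and in at least 2 of the other 7 cases. With the beta-actin ratio as a covariate only Star and Cd24a were called. With the preset correlation 7 lists differed at 24 h, and 0 with an estimated one, where their adjusted p ran from 0.351 to 0.501. The mitotic and meiotic division list had 2 up, 0 down and 21 not passing, 4 up adjusted over the list alone, and adjusted p = 2.68e-07 (adjusted p = 0.351 with an estimated correlation).

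**Figure D4:**
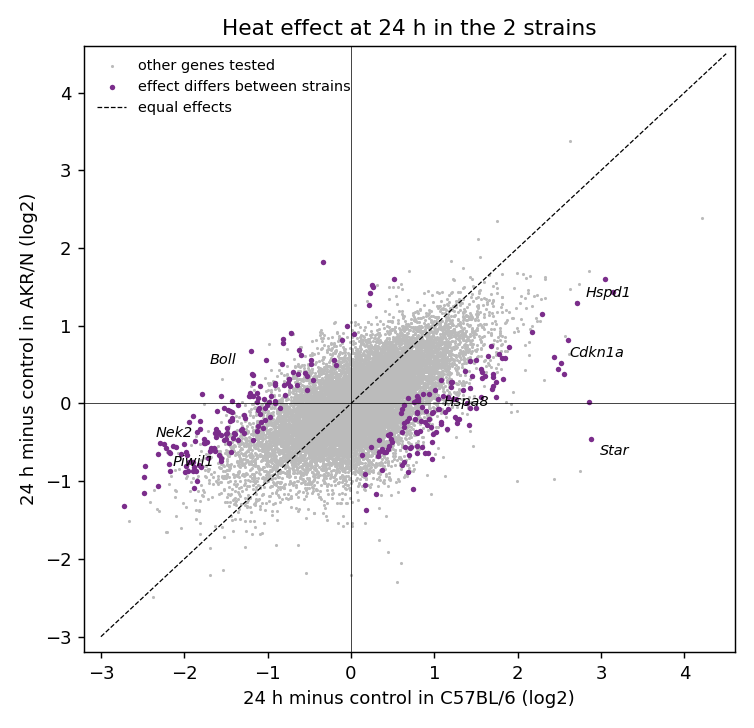
Each point is a gene, with its log2 change at 24 h in C57BL/6 on the horizontal axis and in AKR/N on the vertical axis, and the 277 genes whose effects differed are coloured. The effects correlated across all genes with r = 0.64.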

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

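Of the tests in this part, the differences at single times, the beta-actin covariate, the 8 h baseline, the heat dose, the other probe sets of single genes, the probe sets over all conditions, and mixing with 8 h and 12 h RNA were chosen after the result was seen. The results below were singled out because the heat effect differed between the strains in a test of the interaction. Averaged over times these were 3 genes, Star (−2.07), Cd24a (−1.21) and 1700104B16Rik (0.98), 13 genes differed at any time, 5 at 10 h and 277 at 24 h. As lists over the averaged times, adjusted p was 0.0015 for interferon-stimulated genes, 2.99e-06 for mitotic and meiotic division, 0.0103 for pachytene spermatocytes, 0.0103 for elongating spermatids and 0.0015 for Leydig cells. At 24 h it was 0.00951 for heat shock chaperones, 0.00365 for p53 targets, 4.95e-04 for immediate early and inflammatory genes, 0.00152 for interferon-stimulated genes, 2.68e-07 for mitotic and meiotic division, 4.95e-04 for pachytene spermatocytes and 8.35e-04 for elongating spermatids. With an estimated correlation none of these lists was called, with adjusted p of 0.515 to 0.57 for the averaged times and 0.351 to 0.501 at 24 h.

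Members of the lists that differed at 24 h, as AKR/N minus C57BL/6, were Hspa8 (−0.83), Dnajb4 (−0.75) and Hspd1 (−1.41) among chaperones. Cdkn1a (−1.99), Ccng1 (−1.71) and Gadd45a (−1.65) were among p53 targets, and Txnrd1 (−1.15), Ier3 (−2.17), Cxcl1 (−1.35), Slc2a1 (−1.27) and Hsd17b7 (−1.17) among other stress and metabolic genes. Aurka (1.41) and Nek2 (1.65) were in the mitotic and meiotic division list. Germ cell genes were Cyct (1.22), Spo11 (1.52), Piwil1 (1.48), Spdya (1.15), Boll (1.55) and Tssk6 (−0.97). Somatic genes were Star (−3.33), Gdnf (−1.56), Sox8 (1.60) and Myl9 (0.67). The only other probe set of Txnrd1 went the other way, at 1.33. On the other probe sets the difference was −0.21 to 0.27 for Dnajb4, −0.54 to 0.24 for Hsd17b7, −1.88 to −1.42 for Star, −0.07 for Cdkn1a, −0.82 to −0.16 for Ccng1, −0.16 to 1.64 for Nek2 and −1.63 to 0.93 for Boll.

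A smaller 24 h effect in AKR/N is the first pattern weighed. If the AKR/N controls were out of line, the 24 h difference should shrink below 0.5 of its size with the 8 h arrays as baseline. The median ratio over the 277 genes was 0.786 (95% interval 0.765 to 0.816), and 61 of them were still called, though the shared 24 h arrays keep part of that ratio by construction. A lower heat dose in AKR/N at all times should leave the chaperones lower there at 8 h. Their median difference was −0.025 (−0.12 to 0.083), with 13 of 25 genes lower, and −0.048 and 0.004 at 10 and 12 h. As a set the chaperones thus did not lie lower in AKR/N at those times. These levels cannot decide on the dose, since only 14 genes in C57BL/6 and 6 in AKR/N were called at 8 h. Controls had also differed by a median of 0.11 (−0.18 to 0.22). At 24 h the median difference was −0.28, with 20 of 25 lower. Against its own controls Hspa1b rose by 4.77 in AKR/N and 6.40 in C57BL/6 at 8 h, a difference that was not called. Its levels (AKR/N minus C57BL/6) differed by 0.04 at 8 h and by 1.67 in controls, so that gap lay in the controls. With the beta-actin covariate for RNA quality the 24 h differences had a median ratio of 0.903 (0.875 to 0.927). The covariate's slope rests on differences within pairs of arrays, widest in C57BL/6 at 12 h (2.52 and 3.57). It therefore cannot decide on RNA quality. In C57BL/6 the beta-actin ratio went from 2.14 and 2.46 in controls to 2.84 and 2.58 at 24 h. In AKR/N it went the other way, from 2.92 and 2.39 to 2.14 and 2.17. That covariate ended all calls but 2, because the median SE grew from 0.232 to 0.295 while the median size went from 1.16 to 1.03, so the genes beyond Star and Cd24a are not shown to differ in that fit. RNA quality and a dose difference that the early chaperone levels do not show stay open. The strain itself, timing differences between strains, and the single arrays behind the count of 277 may also contribute. None of these were separated.

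The strain difference in controls is the second pattern. Its technical explanation is sequence differences under single probe sets, which could leave the other probe sets of a gene with smaller effects. Their median ratio to the chosen probe set was 0.292 (0.209 to 0.370) for 240 genes higher in AKR/N and 0.184 (0.103 to 0.301) for 216 genes lower in it. The written prediction, a ratio under 0.25, was met by the second value, though its interval reaches past 0.25. The first value lies between the bounds set beforehand, so sequence and expression cannot be told apart for the genes higher in AKR/N. For comparison, 14 sets of genes called under heat, where no strain is compared, had ratios of 0.168 to 0.507. The lowest was that of 105 genes that fell in AKR/N at 10 h, the next, 0.293, that of 131 genes that rose there, and the other 12 lay at 0.415 or above. Over all conditions the ratio was 0.262 (0.234 to 0.306) for 937 genes lower in AKR/N, under 13 of the 14 sets, and 0.454 (0.413 to 0.494) for genes higher there. A poorer match of probes to the AKR/N sequence predicts that direction and is a candidate explanation for part of the genes lower in AKR/N, as a hypothesis found on the same data. No probe sequence was examined, and the strain itself remains among the open explanations, untested.

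The third pattern is the raised HSP70 genes in AKR/N control replicate 2, with a Hspa1b signal of 493 against 64.7 in replicate 1 and a Hspa1a signal of 383 against 85.2. RNA of heated testes in that control could raise them, at shares of 9.34% for 10 h and 19.97% for 12 h RNA. It should then raise other heat-induced genes, by a predicted median of 0.19 and 0.36, and their observed shifts were −0.13 over 33 genes (−0.32 to −0.01) and −0.20 over 64 genes (−0.33 to −0.02), which argues against both. For 8 h RNA only 4 genes were available, with a shift of −0.049 (−1.05 to 0.71) against a predicted 0.28, too few to decide. Mixing with 24 h RNA could not be computed, since the HSP70 genes were near control levels in AKR/N then, and the reference array, replicate 1, itself had a raised Egr1 signal (461 against 214). A warmer or stressed animal stays open, and no biological explanation was tested because the design has no group for it.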

How the results depend on the processing

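Among the alternatives in this part, the beta-actin covariate, the fit without 2 arrays in doubt and every difference at a single time were chosen after the result was seen. The counts of called genes are given by setting where they moved by more than 1.5 times; where no reason is named, the cause was not tested.

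With quantile normalization 24 genes differed in their heat effect at any time and 3 at 10 h. With median centring the averaged heat difference had 1 gene, AKR/N at 8 h had 14 and the 24 h difference 155. A pseudocount of 1 gave 1 for the averaged difference, 3 for AKR/N at 8 h, 1 for the 10 h difference and 178 for the 24 h difference. A pseudocount of 64 gave 1185 for heat in AKR/N, 6 for the averaged difference, 189 for any time, 19, 780 and 1656 for AKR/N at 8, 10 and 12 h, and 23, 1 and 735 for the differences at 10, 12 and 24 h. Without a filter the averaged difference had 1 and the 24 h difference 155. With the filter at the 60th percentile there were 1103 for heat in AKR/N, 5 for the averaged difference, 88 for any time, 15 and 694 for AKR/N at 8 and 10 h, and 17, 1 and 655 for the differences at 10, 12 and 24 h.

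All probe sets in place of 1 per gene, a larger number of tests by construction, gave 1538 between controls, 7141 between strains over all conditions, 1163 for heat in AKR/N, 6326 for heat in both strains, 30 and 9425 for C57BL/6 at 8 and 24 h, 24 and 1106 for AKR/N at 8 and 10 h, and 14 for the 10 h difference. A variance trend with robust moderation gave 1284 for heat in AKR/N, 38 for the averaged difference, 281 for any time, 28 for C57BL/6 at 8 h, 23, 921 and 1691 for AKR/N at 8, 10 and 12 h, and 2, 37 and 850 for the differences at 8, 10 and 24 h. Fits to only the groups compared, with fewer arrays behind the spread, gave 282 between controls, 84 for heat in AKR/N, 7, 8 and 6 for C57BL/6 at 8, 10 and 12 h, and 0, 1, 9 and 1348 for AKR/N at 8, 10, 12 and 24 h.

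A replicate block gave 1 for the averaged difference, 4 for any time, 2 at 10 h and 157 at 24 h, and the replicate numbers did not pair the samples (median r −0.01 over 45 pairs of groups). With the beta-actin covariate there were 42 for heat in AKR/N, 0 for the averaged difference, 1 for any time, 1091 for C57BL/6 at 12 h, 2, 15 and 1955 for AKR/N at 8, 10 and 24 h, and 0 and 2 for the differences at 10 and 24 h. Without AKR/N control replicate 2 and C57BL/6 12 h replicate 2 together there were 300 for heat in AKR/N, 11 for the averaged difference, 1743 for C57BL/6 at 12 h, and 12, 250 and 616 for AKR/N at 8, 10 and 12 h.

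Leaving out each array in turn, where a lone sample is assumed to vary like the other groups, gave 437 to 872 genes between controls and 3853 to 4432 over all conditions. Heat gave 1021 to 3543 in C57BL/6, 20 to 707 in AKR/N and 2527 to 4308 in both. In C57BL/6 the ranges were 3 to 4, 362 to 675, 1194 to 2588 and 4071 to 4555 at 8, 10, 12 and 24 h, and in AKR/N 1 to 8, 33 to 183, 171 to 878 and 1073 to 2737. The late change gave 1872 to 4643 in C57BL/6 and 909 to 3837 in AKR/N. The averaged difference gave 0 to 7, any time 3 to 27, and the differences at 8, 10, 12 and 24 h gave 0, 0 to 5, 0 to 1 and 2 to 122.

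The genes recomputed under these settings were the named genes and the called members of the lists, the latter added after the first results were seen. Of their 11661 values, 10009 kept their direction and their side of the threshold, 1640 lost a call, 6 gained one and 6, all of genes not called, changed sign. The last were Cdkn1a between controls with quantile normalization (−0.0040) and without C57BL/6 control replicate 2 (−0.15, against 0.28 without replicate 1), Cirbp between controls (−0.064 and 0.26) and under heat in AKR/N (0.0048 and −0.32) without AKR/N control replicate 1 or 2, Hmox1 between controls (−0.17 and 0.92) and Dnajb1 under heat in C57BL/6 (−0.14 and 0.055) without C57BL/6 control replicate 1 or 2. Of lists called in C57BL/6 under heat, all 14 were called with quantile normalization, no filter, a replicate block or without the 2 arrays, and 3 with an estimated correlation. Without the 2 arrays other comparisons lost lists: 7 of 12 were still called for AKR/N at 24 h, 3 of 5 between controls, 5 of 7 over all conditions, 5 of 7 for the 24 h difference, 4 of 5 for the averaged difference and 13 of 14 for heat in both strains. With quantile normalization 11 of 12, 4 of 5 and 6 of 7 were still called for AKR/N at 24 h, the averaged difference and the 24 h difference. Signal over background limits what can be seen: 47.6 to 55.5% of probe sets lay under a signal of 32. The number of arrays limits it too. In simulated data with 2 arrays against 2, 4 to 16% of changes of 0.5 log2 units were found, a range that reflects the random draw.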

Other observations

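The splits of single arrays in this part were planned, while the splits that keep the arrays of a group together, the genes and lists, and the interaction at 24 h were chosen after their values were seen. Star was higher in AKR/N controls and lower in AKR/N at 24 h than in C57BL/6, but not at every time between. Its signal was 81.4 in C57BL/6 and 303 in AKR/N controls (n = 2 each), and 698 in C57BL/6 and 221 in AKR/N at 24 h, with an adjusted p of 3.5e-04 for the interaction. At 8, 10 and 12 h the signals were 243, 540 and 664 in C57BL/6 and 245, 429 and 960 in AKR/N, so at 12 h AKR/N was the higher one again. In C57BL/6 Star was called with Cyp11a1 at 8 h, the earliest time measured, but both calls ended without any 1 of the 4 arrays. The Leydig cell list was called then (adjusted p = 0.00996 with an estimated correlation), with these as its 2 called members of 15.

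At 24 h, with the preset correlation, the division list and pachytene spermatocyte markers fell in both strains while elongating spermatid markers rose in C57BL/6. In whole testes such marker changes may reflect the mix of cells, expression within cells or both, which were not separated. With an estimated correlation 0 of the 13 lists called in C57BL/6 and 0 of the 12 in AKR/N were called at 24 h. In C57BL/6 17 of 23 division genes fell and 1 rose, 15 of 27 pachytene genes fell and 2 rose, and 11 of 26 elongating spermatid genes rose with 0 falling. In AKR/N 8 division genes fell and 0 rose, 9 pachytene genes fell and 1 rose, and 2 of 26 elongating spermatid genes rose with 0 falling (the list's adjusted p = 0.467). Interferon-stimulated genes had 13 up and 0 down of 17 in C57BL/6 at 24 h and 2 up and 0 down in AKR/N. Their list differed between the strains with the preset correlation (adjusted p = 0.00152) and was not called with an estimated one (adjusted p = 0.351), and 0 of the 17 genes differed by themselves over all genes tested in limma, where 5 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone.

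With all 20 arrays treated as exchangeable, chance could be excluded for the count of genes that differed between the strains over all conditions. In a fit of 2 groups, 1 of 100 splits of the arrays, the real one, gave as many called genes, with 1957 against 1288 for the highest other split. For heat over both strains 1 of 100 such splits, the real one, gave as many, with 30 genes against 2. These splits ignore that the 2 arrays of a group may be repeats of the same RNA. With the arrays of a group kept together and the strains swapped within conditions there were 16 splits, too few for a share under 0.05, with 1957 genes against 38 for the highest other. With any 1 group of each strain taken as its control, 2 of 25 splits gave as many as the real 30. The other split, with 4308 genes, set the 24 h arrays of both strains against the rest and points to time after heating as a structure of the samples. That split carries a change after heat and is not a chance draw, so this test cannot decide on chance for heat. All remaining splits gave at most 3 genes.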
